A study of Homo sapiens with 6 samples.

How the data were processed

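RNA of SCC-9 cells was sequenced in 6 libraries, 3 with a control hairpin (shNC) and 3 with a hairpin against MTHFD2 (shMTHFD2). The groups were taken from the sample labels. The design text states 3 biological replicates per condition and calls the modified cells knock-out, while the treatment label describes knockdown by short hairpin plasmids; the term knockdown is used here. How far the cultures were separate is not given in more detail, so p-values measure the spread between these libraries.

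The deposited table lists 17862 genes by Entrez identifier and symbol. Per the file headers it holds FPKM, TPM, read counts and normalized read counts for each library, with group averages. The read counts deposited by the authors are estimated counts, since 53 to 56% of the values per library are whole numbers within a tolerance of 0.001. The FPKM values deposited by the authors are scaled to gene length and sequenced fragments, and the TPM values deposited by the authors sum to the same total in every library within rounding. The normalized read counts deposited by the authors are a signal in which the counts, rounded up, are divided by 1 factor per library, which held for 100% of genes. The aligner, the counting tool, the annotation and the handling of strand are not given in the sources used here. The submitters' processing notes name the mouse build mm10, although the organism label is human; 17793 of the 17862 identifiers are in a human RefSeq gene table, 17524 with the same symbol. Since the build is unclear, no coordinates are given. Counts of paralogs, pseudogene families and overlapping genes are uncertain where the counting could have split reads.

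The libraries held 19332005, 19838989 and 19444110 estimated counts in shNC and 19461166, 18676999 and 19556706 in shMTHFD2, with 16129 to 16858 genes above 0. A count of 0 allows up to 3 counts, 0.151 to 0.161 CPM, for counting error only. The most abundant gene, FN1, took 2.57 to 4.04% of the counts. No libraries were duplicates: a chi-square per degree of freedom between replicates was 3.58 to 83.

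Estimated counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr, libraries scaled by TMM, and groups compared by the quasi-likelihood F test with robust dispersion (edgeR 4.0.16, R 4.3.3), with no covariate. P-values were adjusted by Benjamini-Hochberg over 13710 genes with a threshold of 0.05. The biological coefficient of variation was 16.7%. The SE is the absolute log2 fold change divided by the square root of F. Log2 CPM with a prior count of 2 served for principal components, correlations and list tests.

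Gene lists, 40 in number, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. They covered folate, serine and purine metabolism, stress responses, FOXO biology, the cell cycle, MYC, ribosomes, energy metabolism, cholesterol synthesis, hypoxia, interferon, NF-kB, epithelial and mesenchymal states, signalling targets and markers of other cell types. The 36 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1), two-sided, with a preset correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation was an alternative, as was fry, which tests a list against no change and not against other genes. Mitochondrially encoded transcripts had 0 genes in the table and were not analysed here. Named genes were MTHFD2 and the FOXO family, and the 12 largest rises and 12 largest falls among genes past the threshold, without overlap of the groups, with a mean of at least 5 FPKM and an established symbol. Up to 4 members per list with the smallest adjusted p, and the most abundant marker of each other cell type, were also named; further list members are given where a count called for it and were chosen after their values were seen. Some results of single genes, a fall within the NRF2 list among them, are not reported here.

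Alternatives were each library left out in turn, the replicate number as a block, DESeq2 size factors and upper quartile scaling, no filter or a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) for genes with at least 1 FPKM in 3 libraries, and stricter thresholds. Total counts without scaling, voom with a weight per library, removal of trends with GC content and transcript length, the estimated correlation without a library or after that removal, and the mitochondrial folate list without MTHFD2 were added after seeing the data. Transcript length, GC content and 3' UTR sequences came from GENCODE 29, matched for 99.2% of tested genes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used for tables, sequence words and figures.

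The gene test was run on simulated counts for 13590 genes with the libraries' means and sizes and 200 changed genes. The FOXO target genes outside the 200 were also shifted, by 0.4 on the log2 scale. The test recovered 6% of changes of 0.5 on the log2 scale, 55.2% of changes of 1 and 86.4% of changes of 2, and 5.7% of its calls were false. Counts were drawn independently per gene with the same dispersion in both groups. The false share therefore does not cover correlated genes or the wider spread of the shMTHFD2 libraries. The simulation called 106 genes against 745 in the data, so its adjusted threshold was stricter and its recovery may understate that in the data.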

Results

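Messenger RNA was profiled in SCC-9, an established human line of tongue squamous cell carcinoma, grown in medium with 10% serum and 400 ng/mL hydrocortisone. The study's title concerns MTHFD2 and the ubiquitination and degradation of FOXO1. MTHFD2 is a mitochondrial enzyme of folate-dependent one-carbon metabolism, and FOXO1 is a transcription factor of the forkhead family. Cells carried a short hairpin RNA against MTHFD2 (shMTHFD2) or a control hairpin (shNC), with 3 libraries in each of the 2 groups. The libraries held 18676999 to 19838989 estimated read counts each. Values below are read counts scaled to library size (CPM) as mean ± SD with n = 3 per group. Fold changes are shMTHFD2 over shNC with the SE of the fit and Benjamini-Hochberg adjusted p-values from edgeR's quasi-likelihood test, and "rose" or "fell" means an adjusted p under 0.05.

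The targeted transcript separated the groups in every library. MTHFD2 (Entrez Gene 10797) fell from 191 ± 9.04 CPM in shNC to 49.5 ± 15.2 CPM in shMTHFD2, a log2 fold change of -1.95 (SE 0.21, adjusted p = 0.00924). The mean level in the knockdown was 25.9% of control, and it was 24.6%, 18.7% and 34.5% in shMTHFD2 replicates 1, 2 and 3. FOXO1 (Entrez Gene 2308) was measured at 6.58 ± 0.53 CPM in shNC and 9.75 ± 0.48 CPM in shMTHFD2. Its log2 fold change of 0.57 (SE 0.14) did not pass the threshold over all genes (adjusted p = 0.0584), although all 3 knockdown values lay above all 3 control values. FOXO4 was at 4.6 ± 1.41 against 10.7 ± 3.69 CPM (log2 1.21, SE 0.32, adjusted p = 0.0661), FOXO3 at 55.5 ± 2.58 against 59.9 ± 10.2 CPM (log2 0.11, adjusted p = 0.605), and FOXO6 at 0.68 ± 0.19 against 1.16 ± 0.81 CPM (log2 0.76, adjusted p = 0.373). Adjusted over the list alone, 2 of the 4 FOXO genes passed, FOXO1 and FOXO4, each with an adjusted p of 0.0114. DESeq2 called 2 of the 4 over all genes and limma-voom called 0, and 2 had an unadjusted p under 0.05 in edgeR. The MTHFD2 call ended without shNC replicate 1, 2 or 3 (adjusted p = 0.086, 0.092 and 0.067) and without shMTHFD2 replicate 1 (0.073), with a log2 change between -2.19 and -1.74 over all 6 omissions. FOXO1 passed without shMTHFD2 replicate 2 (adjusted p = 0.034) or replicate 3 (0.03), and in DESeq2 (0.015).

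**Figure D1:**
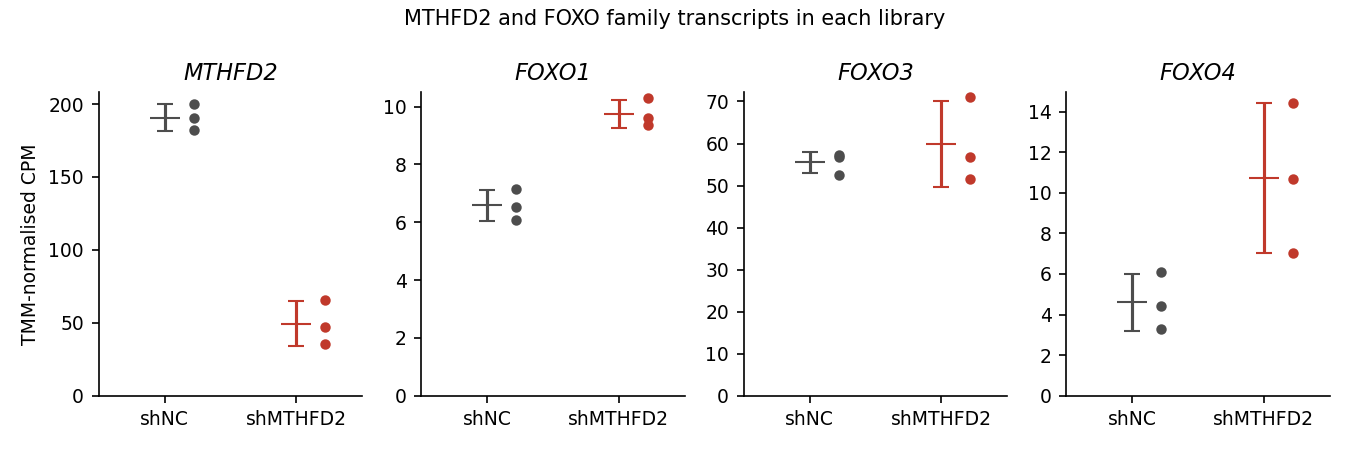
TMM-normalised CPM of MTHFD2, FOXO1, FOXO3 and FOXO4 in the 3 shNC (grey) and 3 shMTHFD2 (red) libraries; points are libraries and the bar is the mean ± SD (n = 3). MTHFD2 averaged 191 CPM in shNC and 49.5 CPM in shMTHFD2, while FOXO1 averaged 6.58 and 9.75 CPM.

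Of 13710 genes tested, 745 changed, 407 of them higher and 338 lower in shMTHFD2. A rise of at least 2-fold was seen for 223 genes and a fall of at least 2-fold for 61. The groups did not overlap for 5181 genes (37.8%, where chance gives 10%), among them all 745 changed genes. The largest rise that met the naming rule was that of TXNIP, a thioredoxin-binding alpha-arrestin, from 117 ± 41.7 to 844 ± 493 CPM (log2 2.85, SE 0.46, adjusted p = 0.0246). COL6A2, a collagen VI chain, rose from 20.5 ± 2.51 to 137 ± 18.4 CPM (log2 2.75, SE 0.15, adjusted p = 0.00184). The carbonic anhydrase CA9 rose from 167 ± 29.3 to 896 ± 352 CPM (log2 2.42, SE 0.32, adjusted p = 0.0159). The gelatinase MMP9 rose by 2.24 on the log2 scale (SE 0.23), the invariant chain CD74 by 2.14 (SE 0.18), the neuronal enolase ENO2 by 2.12 (SE 0.17) and the elongation factor EEF1A2 by 2.08 (SE 0.45). DEPP1 (1.88), the alpha-arrestin ARRDC4 (1.76), CORO6 (1.66), the complement inhibitor SERPING1 (1.60) and PNRC1 (1.5) completed the 12 largest rises, with adjusted p-values from 0.00184 to 0.0445 over the 12.

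The largest fall that met the naming rule was that of FGFBP1, a secreted carrier of fibroblast growth factors, from 89.2 ± 3.92 to 15.1 ± 9.41 CPM (log2 -2.56, SE 0.47, adjusted p = 0.0329). SERPINB2, the plasminogen activator inhibitor 2, fell from 257 ± 27.0 to 52.9 ± 22.7 CPM (log2 -2.28, SE 0.29, adjusted p = 0.0148). The prostaglandin receptor PTGER4 (log2 -2.02, SE 0.26) and the cyclooxygenase PTGS2 (log2 -1.60, SE 0.19) fell. The activin antagonist FST (log2 -1.78), the microtubule plus-end protein MAPRE1 (-1.65), the polyamine enzyme ODC1 (-1.51), the small GTPase RND3 (-1.47), the receptor kinase AXL (-1.42) and the glutathione-degrading enzyme CHAC1 (-1.40) also fell. ASDURF (log2 -1.73, SE 0.28) is encoded on the transcript of ASNSD1, with which it can share reads, and its value is uncertain. With MTHFD2 these make up the 12 largest falls, whose adjusted p-values ran from 0.00454 to 0.0329.

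**Figure D2:**
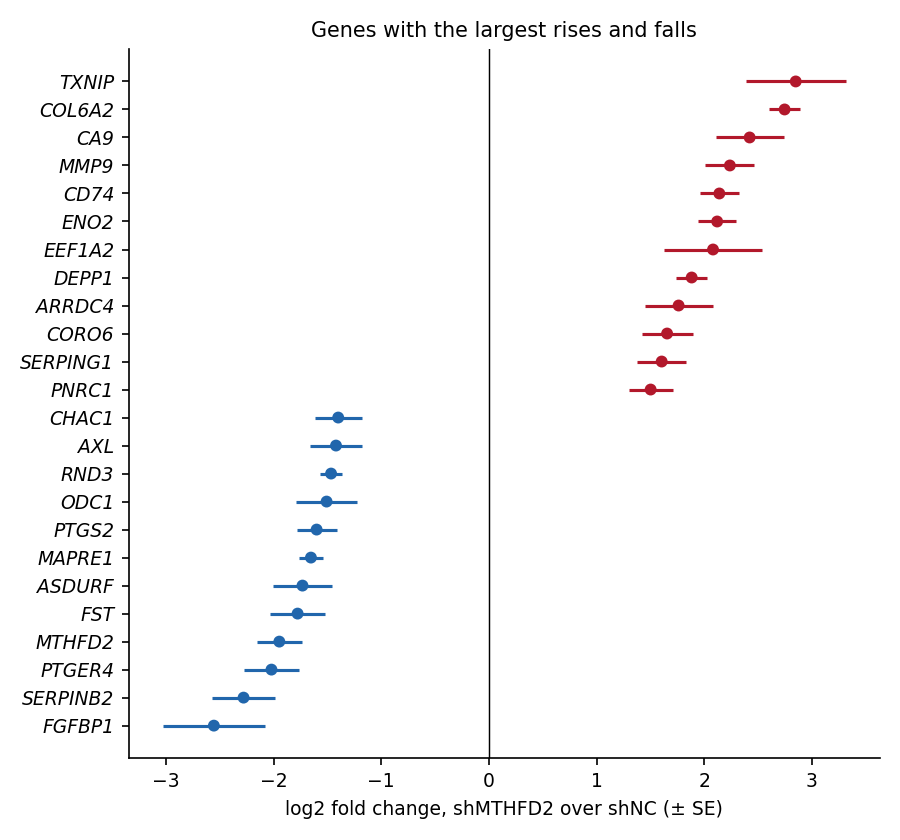
Log2 fold change (shMTHFD2 over shNC, n = 3 per group) of the 12 largest rises and 12 largest falls that met the naming rule; points are fitted values and lines ± 1 SE. TXNIP lies highest at 2.85 and FGFBP1 lowest at -2.56.

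The number of calls depended on single libraries. Without shNC replicates 1, 2 and 3 in turn, 1, 1 and 5 genes passed. Without shMTHFD2 replicates 1, 2 and 3 in turn, 27, 1968 and 3651 passed. All 745 changed genes kept their original direction in each of these fits. Their groups did not overlap with all 6 libraries, so leaving out 1 could hardly reverse them, and this does not measure robustness. Of the 24 largest rises and falls, 1, 1, 4, 7, 24 and 24 stayed past the threshold in the same order of omissions, and COL6A2 did so in all 6. The balance of calls moved with the scaling, from 54.6% higher to 68.4% with upper quartile scaling (455 higher, 210 lower) and to 66.1% with total counts (449 higher, 230 lower). Correlations of log2 CPM across genes were 0.992 to 0.994 within shNC, 0.958 to 0.984 within shMTHFD2 and 0.9459 to 0.9836 between the groups. The lowest within shMTHFD2 was between replicates 2 and 3. shMTHFD2 replicate 3 was closer to the shNC libraries (0.9815 to 0.9836) than to replicate 2, and closest to replicate 1 (0.9843). On the first principal component (63% of the variance) shMTHFD2 replicate 2 stood apart at 61.3, against 20.7 and -3.2 for shMTHFD2 replicates 1 and 3 and -34 to -19.2 for shNC. On the second (17.5%) shMTHFD2 replicate 3 stood apart at -33.6, against -11.1 and 15 for shMTHFD2 replicates 1 and 2 and 8.5 to 11.1 for shNC.

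**Figure D3:**
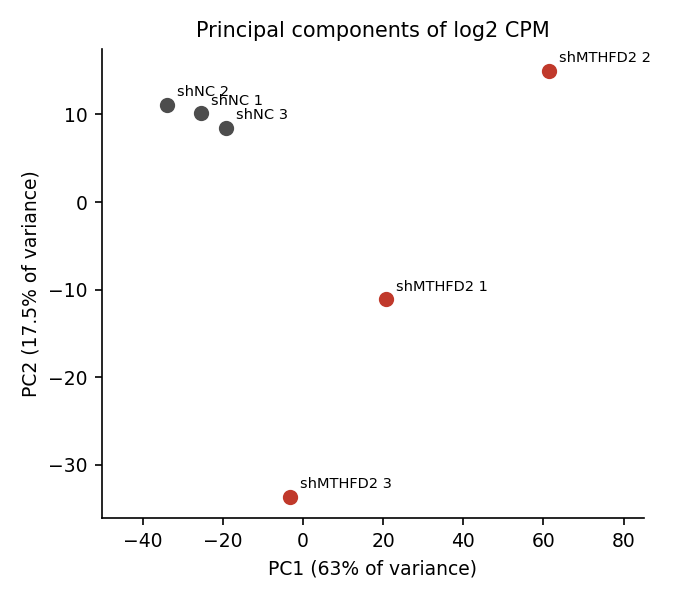
First and second principal components of log2 CPM (13710 genes) for the 3 shNC (grey) and 3 shMTHFD2 (red) libraries, each point 1 library. The shNC libraries lie together between -34 and -19.2 on the first component, and shMTHFD2 replicate 2 lies at 61.3. shMTHFD2 replicate 3 lies at -33.6 on the second component.

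Of 28 tested targets of ATF4, the transcription factor of the amino acid response, 12 fell and 1 rose (16 fell and 1 rose adjusted over the list alone), with a mean log2 change of -0.48. TRIB3 fell from 112 ± 3.98 to 46.9 ± 4.95 CPM (log2 -1.25, SE 0.10, adjusted p = 0.00575), and both chains of the large neutral amino acid transporter fell, SLC7A5 from 4195 ± 333 to 1725 ± 379 CPM (log2 -1.28, SE 0.17) and SLC3A2 from 831 ± 11.1 to 420 ± 58.6 CPM (log2 -0.98, SE 0.12). The list passed the camera test with a preset correlation (adjusted p = 5.1e-07; adjusted p = 0.26 with an estimated correlation). In serine synthesis and uptake, 3 of 7 genes fell (4 adjusted over the list alone): the transporters SLC1A5 (log2 -1.19, SE 0.15) and SLC1A4 (-0.75, SE 0.15) and the phosphatase PSPH (-0.86, SE 0.15). That list passed camera with an adjusted p of 0.00034 (adjusted p = 0.36 with an estimated correlation).

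Among folate enzymes, MTHFD2 was the only one edgeR called over all genes with all 6 libraries. Without shMTHFD2 replicate 2, 3 mitochondrial and 3 cytosolic folate enzymes fell. Without shMTHFD2 replicate 3, 4 mitochondrial and 5 cytosolic folate enzymes fell and 1 mitochondrial one rose. In the mitochondrial list, 1 of 10 fell, MTHFD2 itself (4 fell and 1 rose adjusted over the list alone), DESeq2 called 2 lower and 1 higher, and the glycine cleavage gene GCSH was next with log2 -0.59 (adjusted p = 0.0605). The list's mean was -0.35 (camera adjusted p = 0.016; adjusted p = 0.26 with an estimated correlation). Without MTHFD2, the targeted gene, the other 9 members had a mean of -0.17 and did not pass (camera adjusted p = 0.069; adjusted p = 0.36 with an estimated correlation). Of 12 cytosolic folate enzymes, edgeR called 0 over all genes, with 5 lower at an unadjusted p under 0.05, 2 lower in DESeq2 and 0 in limma-voom, and 4 fell adjusted over the list alone. Their mean was -0.34 (camera adjusted p = 0.0084; adjusted p = 0.39 with an estimated correlation). In de novo purine synthesis, a folate-dependent pathway, 2 of 13 fell (3 adjusted over the list alone), IMPDH1 (log2 -0.61, SE 0.08) and PAICS (-0.65, SE 0.10). The purine list's mean was -0.05 (camera adjusted p = 0.044; adjusted p = 0.39 with an estimated correlation). Its mean turned to 0.01 with upper quartile scaling (adjusted p = 0.075) and 0.02 without shMTHFD2 replicate 3 (0.31), and its call also ended with total counts (0.059), with FPKM (0.054), with GC and length trends removed (0.08) and without shNC replicate 2 (0.075). Without shMTHFD2 replicate 2 its mean was -0.08 (adjusted p = 0.029; adjusted p = 0.45 with an estimated correlation).

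The list of FOXO target genes had a mean log2 change of 0.43 and passed camera with an adjusted p of 0.00034 (adjusted p = 0.23 with an estimated correlation). Of 34 tested, 8 rose and 0 fell over all genes, against 16 that rose and 3 that fell adjusted over the list alone. PDK4, a kinase that inhibits pyruvate dehydrogenase, rose from 1.33 ± 0.17 to 9.34 ± 2.00 CPM (log2 2.80, SE 0.24, adjusted p = 0.00575). MXI1 rose by 0.75 (SE 0.11), the ubiquitin ligase FBXO32 by 0.59 (SE 0.11) and TXNIP as given above. The others that rose were GABARAPL1, CDKN1B, RICTOR and TNFSF10. The list's mean over each knockdown library was 0.37, 0.48 and 0.37. At an unadjusted p under 0.05, 18 members were higher and 3 lower in edgeR, and DESeq2 called 15 higher and 1 lower. Of 8 ligases and deubiquitinases reported for FOXO1, FBXO32 rose and COP1 fell (log2 -0.50, SE 0.10), with 1 risen and 2 fallen adjusted over the list alone (camera adjusted p = 0.12).

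Of 24 genes of cholesterol synthesis, 8 fell and 0 rose (18 fell and 1 rose adjusted over the list alone), with a mean of -0.45. HMGCS1 fell from 112 ± 10.5 to 47.7 ± 2.96 CPM (log2 -1.23, SE 0.11, adjusted p = 0.00575), CYP51A1 from 103 ± 2.70 to 60.6 ± 2.77 CPM (log2 -0.77, SE 0.09), FDFT1 by 0.74 on the log2 scale and DHCR7 by 0.83. The list passed camera with an adjusted p of 2.7e-08 (adjusted p = 0.088 with an estimated correlation). Of 21 hypoxia targets, 9 rose and 0 fell (12 rose and 1 fell adjusted over the list alone), with a mean of 0.66. BNIP3L rose from 69.1 ± 0.15 to 117 ± 2.97 CPM (log2 0.76, SE 0.08, adjusted p = 0.00842), the collagen prolyl hydroxylase P4HA1 by 0.95 (SE 0.12) and CA12 by 1.07 (SE 0.14), beside CA9. The hypoxia list passed camera with an adjusted p of 2.1e-07 (adjusted p = 0.13 with an estimated correlation). Of 22 glycolysis genes, ENO2 alone rose (4 rose and 1 fell adjusted over the list alone), while PKM was at log2 -0.65 (adjusted p = 0.0539) and the list did not pass (camera adjusted p = 0.43). Without shMTHFD2 replicate 2 the glycolysis list passed (adjusted p = 0.039; adjusted p = 0.35 with an estimated correlation).

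Of 25 MYC targets, 9 fell and 0 rose (14 fell adjusted over the list alone), with a mean of -0.40, among them the nucleolar proteins NOP56 (log2 -0.85, SE 0.12) and MRTO4 (-0.64, SE 0.11) and the mitochondrial chaperonin HSPE1 (-0.63, SE 0.11). The list passed camera with an adjusted p of 3.5e-07 (adjusted p = 0.26 with an estimated correlation). In the list of G1/S and DNA replication, 33 of 35 genes had a negative fold change and the mean was -0.47, but edgeR called 0 genes over all genes and 0 adjusted over the list alone. Over all genes 9 fell without shMTHFD2 replicate 2 and 22 without replicate 3. With all 6 libraries 18 of the 35 were lower at an unadjusted p under 0.05, DESeq2 called 9 lower and limma-voom 0. The list passed camera with an adjusted p of 1.8e-07 (adjusted p = 0.49 with an estimated correlation), and its mean was -0.44, -0.95 and -0.16 in shMTHFD2 replicates 1, 2 and 3 and -0.27 over the fit without replicate 2 (adjusted p = 4.6e-08; adjusted p = 0.43 with an estimated correlation). Of 33 genes of G2/M and mitosis, BIRC5 (log2 -0.52, SE 0.09) and CDC20 (-0.47, SE 0.10) fell (4 fell adjusted over the list alone). That list passed camera with an adjusted p of 0.0011 (adjusted p = 0.73 with an estimated correlation), with means of -0.31, -0.50 and 0.05 in the 3 knockdown libraries. Its mean was -0.10 without shMTHFD2 replicate 2 (adjusted p = 0.034; adjusted p = 0.81 with an estimated correlation) and -0.38 without replicate 3 (1.1e-06; adjusted p = 0.61 with an estimated correlation). Of 37 nuclear-encoded genes of oxidative phosphorylation, NDUFB10 (log2 -0.43, SE 0.09) and ATP5MC1 (-0.37, SE 0.08) fell (6 adjusted over the list alone), with a mean of -0.19 (camera adjusted p = 1e-05; adjusted p = 0.36 with an estimated correlation).

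**Figure D4:**
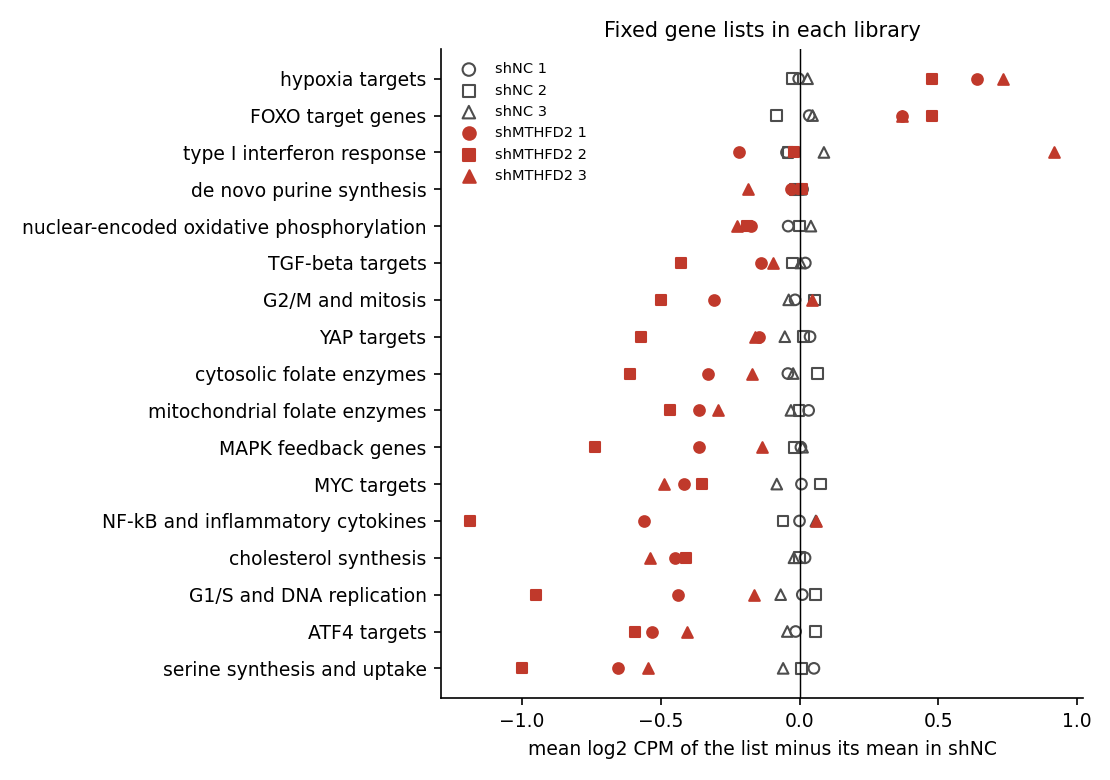
Mean log2 CPM of the 17 lists that passed the camera test with a preset correlation, per library, minus the mean over shNC; open grey symbols are shNC and filled red symbols shMTHFD2, with replicates 1, 2 and 3 as circle, square and triangle. Hypoxia targets lie at 0.64, 0.48 and 0.73 in the knockdown libraries, while the interferon list lies at 0.92 in replicate 3 and at -0.22 and -0.02 in replicates 1 and 2.

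Inflammatory and interferon lists differed between knockdown libraries. Of 23 NF-kB and cytokine genes, PTGS2 fell (also 1 adjusted over the list alone), and the list's mean of -0.43 (camera adjusted p = 0.044; adjusted p = 0.86 with an estimated correlation) combined values of -0.56, -1.19 and 0.06 in shMTHFD2 replicates 1, 2 and 3. Its call ended without shMTHFD2 replicate 1 (adjusted p = 0.062), without shMTHFD2 replicate 2 (mean -0.19, 0.23), without shNC replicate 3 (0.085), with FPKM (0.061) and with GC and length trends removed (0.1). The mean was -0.80 without shMTHFD2 replicate 3 (adjusted p = 0.00046; adjusted p = 0.68 with an estimated correlation). Of 36 type I interferon response genes, the RNA sensor IFIH1 rose from 36.4 ± 1.83 to 65.8 ± 11.5 CPM (log2 0.85, SE 0.14; also 1 adjusted over the list alone). The list's mean was 0.36 (camera adjusted p = 0.044; adjusted p = 0.86 with an estimated correlation). It was -0.08 without shMTHFD2 replicate 3 (adjusted p = 0.31), where 10 of the 36 genes fell and 2 rose. The call also ended without shNC replicate 1 (0.068) or 2 (0.053). It ended as well with upper quartile scaling (0.089), total counts (0.083), DESeq2's size factors (0.051) and no filter (0.059). The mean was 0.58 without shMTHFD2 replicate 1 (adjusted p = 5.3e-05; adjusted p = 0.66 with an estimated correlation).

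Of 17 TGF-beta targets, CCN1 fell (log2 -0.57, SE 0.10; 4 fell and 1 rose adjusted over the list alone), with a list mean of -0.20 (camera adjusted p = 0.034; adjusted p = 0.49 with an estimated correlation). Of 23 YAP targets, AXL and CCN1 fell (3 adjusted over the list alone), with a mean of -0.29 (camera adjusted p = 0.044; adjusted p = 0.81 with an estimated correlation). Without shMTHFD2 replicate 2 neither list passed (means -0.10 and -0.14, adjusted p = 0.15 and 0.18), and the YAP list also did not pass without shMTHFD2 replicate 3 (0.063). Neither passed with a mean of at least 5 CPM (0.064 and 0.14) or with FPKM (0.061 and 0.13), nor the TGF-beta list with no filter (0.1). Of 18 MAPK feedback genes, edgeR called 0 over all genes with all 6 libraries, 6 lower without shMTHFD2 replicate 2 and 9 lower without replicate 3. With all 6 libraries, 7 of the 18 were lower and 1 higher at an unadjusted p under 0.05. DESeq2 called 6 of these genes lower and limma-voom 0, and 2 fell adjusted over the list alone. Their mean was -0.35 (camera adjusted p = 0.012; adjusted p = 0.39 with an estimated correlation), and -0.21 without shMTHFD2 replicate 2 (0.0017; adjusted p = 0.35 with an estimated correlation). In all, 17 of 36 lists passed with the preset correlation, 14 lower and 3 higher. Other splits of the 6 libraries into 3 against 3 put 8 to 17 lists past the same threshold. The number of lists passed therefore does not by itself set the real groups apart. With the real groups and an estimated correlation 0 lists passed, and 6 had an unadjusted p under 0.05. For the cholesterol, FOXO target and mitochondrial folate lists the estimate was 0, 0.014 and -0.015, near or under the preset 0.01. Correlated members therefore do not account for the larger p-values of those lists in that setting. The fry test, which asks whether a list's genes move on balance 1 way and does not compare them with other genes, called 14 lists, of which 10 were among the 17. The 4 others that fry called were the lists of matrix proteases (adjusted p = 0.033), heat shock genes (0.035), mesenchymal markers (0.035) and FOXO1 ligases and deubiquitinases (0.01). Fry did not call 7 of the 17. These were G1/S and DNA replication (fry adjusted p = 0.15), G2/M (0.29), MAPK feedback (0.13), TGF-beta (0.15), YAP (0.29), NF-kB (0.47) and interferon (0.6).

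The other lists did not pass camera with the preset correlation in the main fit. With a mean of at least 5 CPM 17 lists passed although the TGF-beta and YAP lists did not, so others passed there. With FPKM 14 passed although 4 of those called in the main fit did not, so another list passed there too. Which lists these were is not reported here. With GC and length trends removed, the ribosomal list passed (mean 0.09, adjusted p = 0.014; adjusted p = 0.83 with an estimated correlation). Of 25 NRF2 targets, 6 rose (also 6 adjusted over the list alone), among them the ferritin chains FTH1 (log2 0.66, SE 0.09) and FTL (0.61, SE 0.12) and the reductase AKR1C1 (1.45, SE 0.24). AKR1C1, AKR1C2 and AKR1C3 are near-identical copies, and FTH1 and FTL have many pseudogenes, so their counts are uncertain. The NRF2 list's mean was 0.13 and its median -0.002 (camera adjusted p = 0.46). The mean was -0.02 without shMTHFD2 replicate 3 (adjusted p = 0.88) and 0.23 without replicate 2 (0.081). Of 25 p53 targets, TP53INP1 (log2 1.00, SE 0.12) and BTG2 (1.26, SE 0.19) rose while AEN (-0.66, SE 0.09) and SESN2 (-0.81, SE 0.18) fell (2 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.94). Of 16 matrix proteases and inhibitors, MMP9, TIMP2 (log2 0.58, SE 0.10) and KLK5 (0.51, SE 0.09) rose and KLK10 fell (-0.50, SE 0.10), with the same numbers adjusted over the list alone (camera adjusted p = 0.075). Without shMTHFD2 replicate 2 the protease list passed (adjusted p = 0.015; adjusted p = 0.31 with an estimated correlation). Of 24 mesenchymal markers, MMP9 and ITGA5 (log2 0.58, SE 0.10) rose and AXL fell (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.12). In that omission the mesenchymal list passed (adjusted p = 0.035; adjusted p = 0.35 with an estimated correlation).

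Among 11 heat shock genes, HSPE1 and HSPA8 fell (4 adjusted over the list alone; camera adjusted p = 0.088). Of 23 apoptosis regulators, BMF rose (log2 1.36, SE 0.22) and BAD fell (-0.49, SE 0.10), with 5 risen and 4 fallen adjusted over the list alone (camera adjusted p = 0.8). Of 18 immediate early genes, BTG2 rose and ATF3 fell (2 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.75). CLDN4 rose (log2 0.88, SE 0.18) among 21 epithelial adhesion genes (also 1 adjusted over the list alone; camera adjusted p = 0.75). SPRR2A, a cornified envelope gene with close paralogs, fell from 1.78 ± 0.30 to 0.27 ± 0.18 CPM (log2 -2.68, SE 0.46, adjusted p = 0.0271) among 16 keratinocyte differentiation genes (3 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.75). SGK1 fell (log2 -1.17, SE 0.25) among 14 glucocorticoid receptor targets (2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.96), where the mean of 0.14 and median of 0.03 were positive and camera's direction was down. NKD1 rose (log2 1.10, SE 0.22) among 9 WNT targets (2 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.8), whose mean was 0.38, whose median was -0.07 and whose camera direction was down.

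For 4 further lists edgeR called 0 members with all 6 libraries, over all genes and adjusted over the list alone unless given. Without shMTHFD2 replicate 3, 12 ribosomal and 4 basal keratinocyte genes rose over all genes, and 1 unfolded protein response gene fell. Without shMTHFD2 replicate 2, 3 basal keratinocyte genes rose and 1 fell, and 1 unfolded protein response gene fell. Of 42 cytosolic ribosomal protein genes, 1 was lower at an unadjusted p under 0.05 and DESeq2 and limma-voom called 0 (mean 0.08, camera adjusted p = 0.18). The ribosomal list's mean was 0.21 without shMTHFD2 replicate 3 (adjusted p = 7.2e-06; adjusted p = 0.68 with an estimated correlation). It was 0.03 without replicate 1 (0.82) and 0.02 without replicate 2 (0.98), and its members were strongly correlated (estimated correlation 0.901). Of 17 genes of the ER unfolded protein response, 2 were lower at an unadjusted p under 0.05 and DESeq2 and limma-voom called 0 (mean 0.02, median -0.06, camera direction down, adjusted p = 0.46). Of 16 basal keratinocyte genes, 5 were higher and 1 lower at an unadjusted p under 0.05, DESeq2 called 3 higher and limma-voom 0 (mean 0.02, camera adjusted p = 0.58). Of 6 replication-dependent histone genes, 0 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0 (camera adjusted p = 0.75).

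Markers of other cell types showed no call in edgeR over all genes. Of 6 fibroblast markers, 2 were higher at an unadjusted p under 0.05, DESeq2 called 1 higher, limma-voom 0, and 1 rose adjusted over the list alone (camera adjusted p = 0.18). Without shMTHFD2 replicate 2 their mean was 0.62 (adjusted p = 0.046; adjusted p = 0.35 with an estimated correlation). The most abundant, FAP, was at 50.2 ± 2.54 against 62.3 ± 10.2 CPM (adjusted p = 0.168). Of 8 markers of simple and glandular epithelium, 2 were lower and 1 higher at an unadjusted p under 0.05 and DESeq2 and limma-voom called 0 (camera adjusted p = 0.46); KRT8 was at 521 ± 29.3 against 422 ± 51.3 CPM (adjusted p = 0.139). The 4 leukocyte and 3 endothelial markers tested were too few for a list test, and 0 of them had an unadjusted p under 0.05 or a call in DESeq2 or limma-voom. CD68 was at 106 ± 6.08 against 131 ± 24.3 CPM (adjusted p = 0.205) and PECAM1 at 0.94 ± 0.38 against 0.98 ± 0.44 CPM (adjusted p = 0.937).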

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

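Voom with library weights, total counts, GC and length removal, the estimated correlation without a library or after that removal, and the mitochondrial folate list without MTHFD2 were chosen after seeing the data. All 745 changed genes kept their direction in every refit that included them (613 under the stricter filter, 643 with FPKM). They were picked as changed in the same libraries, with groups that did not overlap, so a reversal was hardly possible. The count of changed genes ranged from 1 to 3651 over single omitted libraries (higher 1 to 1895, lower 0 to 1756). DESeq2 called 2023 (1106 higher, 917 lower), weighted voom 5823 (2637 and 3186), an adjusted p under 0.01 left 33 (20 and 13), and a log2 change of at least 1 left 284 (223 and 61). Upper quartile scaling left 210 lower. Other settings gave 520 to 713 genes; the cause of these differences was not tested. Correlations of same-numbered deviations were 0.001, -0.237 and -0.187. They showed no pairing by replicate number, but with 3 libraries per group and a wide spread within shMTHFD2 they cannot exclude it. With a replicate block 16 genes passed (11 higher, 5 lower) and MTHFD2 had log2 -1.99 (adjusted p = 0.05). In that fit 16 lists passed, the purine list losing its call (adjusted p = 0.076).

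MTHFD2 stayed lower throughout, from -2.189 to -1.742 over omitted libraries. FOXO1 ranged from 0.519 to 0.621 over omitted libraries (adjusted p from 0.03 to 0.26) and was 0.351 on log2(FPKM + 1) (adjusted p = 0.081), a scale that understates changes of low genes; it passed in DESeq2 (0.58, adjusted p = 0.015) and weighted voom (0.664, adjusted p = 0.00082), and over all settings its adjusted p ran from 0.00082 to 0.26. The FOXO target list kept its mean of 0.428 with an estimated correlation but not its call (adjusted p = 0.23), nor without shMTHFD2 replicate 2 as well (0.397, adjusted p = 0.31). In both settings 0 lists passed. With all 6 libraries the FOXO target list's estimated correlation was 0.014, near the preset 0.01, so correlated members do not account for the lost call. With an estimated correlation it also did not pass in the other 5 omissions or after GC and length removal (adjusted p = 0.14). In every list setting with the preset correlation, and in fry, which does not compare with other genes, the FOXO target list passed. Without MTHFD2 the mitochondrial folate list lost its call (-0.173, adjusted p = 0.069; adjusted p = 0.36 with an estimated correlation). Without shMTHFD2 replicate 3 the interferon list reversed (-0.077, adjusted p = 0.31). The list tests do not use DESeq2 or voom, and a pseudocount does not apply to the count test. In a simulation with fewer changed genes, and so a stricter adjusted threshold than in the data, changes of 0.5 on the log2 scale were rarely recovered (6%).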

Other observations

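The families in the next 2 paragraphs, the tests of graded knockdown, read-through RNA and culture state, the shuffles and shares for sequence words, and the comparisons within list members were chosen after the result was seen.

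Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, held 9 of 18 genes that fell and 0 that rose, with a mean log2 change of -0.30 and values of -0.31, -0.27 and -0.36 in the 3 knockdown libraries. GARS1 fell by 0.74 (SE 0.12), TARS1 by 0.63 and NARS1 by 0.62 on the log2 scale. Among 15 families examined, 14 had enough members to test, and the cytosolic synthetases passed camera with an adjusted p of 4.2e-05 (adjusted p = 0.21 with an estimated correlation). Passing was common: proteasome (0.00054), YPEL (0.00077), lysosomal (0.0016), chaperonin (0.0029) and nuclear transport (0.0046) families also did. Mitochondrial synthetases (0 of 17 called, 0.36), alpha-arrestins (0.099), carbonic anhydrases (0.1), translation factors (0.19) and fatty acid oxidation (0.3) did not. The translation factors were picked by symbol, and that set also holds kinases, methyltransferases and binding proteins of these factors. With an estimated correlation the adjusted p ran from 0.21 to 0.57 over the families. In fatty acid synthesis, SCD fell by 0.98 (SE 0.15) and FASN by 0.72 (SE 0.12), 2 of 11 genes (camera adjusted p = 0.00054; adjusted p = 0.21 with an estimated correlation).

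HLA-B rose by 1.63 on the log2 scale (SE 0.16), HLA-F by 0.93 and HLA-C by 0.59, 3 of 6 genes in a family of 5 class I heavy chains, which are close paralogs, and B2M (camera adjusted p = 4.2e-05; adjusted p = 0.21 with an estimated correlation). The family's mean was 0.56, 0.81 and 0.85 in shMTHFD2 replicates 1, 2 and 3, whereas the interferon list was at -0.22, -0.02 and 0.92. Of 24 collagens, 6 rose and 2 fell, among them COL6A1 (0.93, SE 0.10) beside COL6A2 (camera adjusted p = 0.0046; adjusted p = 0.21 with an estimated correlation). YPEL2 (1.92) and YPEL3 (1.02) rose, 2 of 5 YPEL genes.

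The 6 libraries make 10 splits, the real one included, too few for a share under 0.05. The real split called 745 genes and the highest other split 0 (up to 1217 genes at an unadjusted p under 0.05), so 1 of 10 splits gave as many. For lists, 2 of 10 splits gave 17 or more, and the splits other than the real one gave 8 to 17. Passing camera with the preset correlation was therefore common in any grouping and does not by itself set the real split apart. For the FOXO target list the real p was 7.08e-05 and the smallest other 0.00354, so 1 of 10 splits gave one as small.

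shMTHFD2 replicate 2 stood apart from the other 5 libraries on the first principal component, and shMTHFD2 replicate 3 stood apart on the second. shMTHFD2 libraries varied more than shNC libraries. Removing trends with GC content and transcript length left the ratio of mean squared deviations, shMTHFD2 over shNC, at 3.46, against 3.36 before. The bootstrap interval of 3.15 to 3.79 resampled genes, which are not independent, and not libraries. This argues against such a bias as the whole cause of the wider spread in shMTHFD2. The ratio pools the shMTHFD2 libraries, so it does not test replicate 2 alone. For more read-through RNA in shMTHFD2 replicate 2, the median log2 difference over 54 annotated read-through genes was -0.08. The 99th percentile of matched random gene sets was 0.332. Single genes ran from -5.317 to 2.859, and their counts can share reads with the genes they overlap, so this does not decide the question. A graded depth of knockdown stays open: the distance from shNC followed the order of MTHFD2 loss in 3 of 3 libraries, which chance gives in 1 of 6 orders.

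The hypoxia, cholesterol, DNA replication, MYC and ATF4 lists passed camera with the preset correlation, and adjusted p = 0.13, 0.088, 0.49, 0.26 and 0.26 with an estimated correlation. In DNA replication edgeR called 0 members with all 6 libraries, and DESeq2 9. Fry did not call that list (adjusted p = 0.15). All 5 stayed past the preset threshold after trends with GC content and length were removed. Passing it was common in other splits too, and with an estimated correlation their adjusted p after removal was 0.14, 0.14, 0.58, 0.37 and 0.37. Their mean changes in log2 CPM were 0.617, -0.466, -0.517, -0.417 and -0.51 before removal and 0.581, -0.505, -0.557, -0.447 and -0.581 after. The means, and not the passing, argue against that bias as the main source of these changes. A culture state that also varies between dishes may contribute: the difference between 2 shNC libraries correlated across genes, which are not independent replicates, with the knockdown's change over the other shNC library, with absolute r of 0.32, 0.203 and 0.155, where the rule set for this test was over 0.2 in at least 2. Without shMTHFD2 replicate 2, r was 0.26, 0.188 and -0.097, and only 1 of 3 was over 0.2. Over the 133 members of the lists r was 0.513, 0.542 and -0.245. The shNC range was 8.6 to 37.5% of the change per list, so the control spread was smaller than the change. The knockdown libraries could spread more: the DNA replication list was at -0.437, -0.949 and -0.164 in shMTHFD2 replicates 1, 2 and 3. Its smallest gap between the groups was 0.095, against 0.268 to 0.447 for the other lists. A direct effect of MTHFD2 loss also stays open and was not tested.

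Genes other than MTHFD2 fell, and off-target seed matches of the hairpin may account for part of this. Of 16240 words of 7 bases tested in 3' UTRs, the most negative association with the fold change (z -4.61, against 3.54 for the most positive) belonged to a word of the MTHFD2 transcript, TCACTCC, which met the condition set before the result was seen. The evidence is weak: 3485 of the words lie in that transcript, and the word goes with a change of only -0.059 on the log2 scale over 1563 genes. A permutation test that shuffled fold changes over genes 1000 times gave p = 0.02, treating genes as independent. It compared the most negative z over all words, so it does not test whether the word belongs to MTHFD2. The word was in 22.7% of 330 fallen genes and 11.4% of other genes, a comparison not corrected for UTR length and made on the data that picked the word, and besides MTHFD2, MAPRE1 was the only gene found with it among the 12 largest falls. The hairpin's sequence was not used here, and a second hairpin was not analysed here.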
